A study of Mus musculus with 6 samples.

How the data were processed

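RNA was measured in 6 libraries of mouse bone marrow-derived macrophages, 3 labelled WT and 3 labelled PTEN KO, all differentiated for 7 days with GM-CSF. Per the labels' protocols, total RNA was taken up in TRIzol, quantified on a NanoDrop and checked for integrity on a Bioanalyzer. The genotype field of the labels calls the second group a knockdown, whereas the titles and the series description speak of knockout, and the libraries are called PTEN KO here. No label says how the Pten gene was altered, or whether the 3 samples of a group came from separate mice or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

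The deposited table gave 1 expression value per gene symbol and library for 17004 genes, and 1 p-value per gene. Per the file headers the values are called only expression. They were treated as FPKM that the authors had computed, because the 6 values of every gene stood in whole-number ratios once each library was divided by a factor of its own, as read counts scaled by depth and gene length do. With a relative tolerance of 1e-11 and at most 2000000 reads per gene, whole-number ratios were found for 17004 of the 17004 genes, which covers 100.0% of the values above 0. After relative noise of 1e-06 was added to the values, 17 genes met the same limits. A gene whose 6 read numbers share a common factor would be given too few reads, which chance produces for about 1.70% of genes. The submitters' processing notes list the mouse build mm10, DESeq2 and R 3.2.0, without saying which step each was used for. The aligner, the counting program, its annotation and its use of strand are not given in the sources used here. Reads shared by near-identical genes (Lyz1 with Lyz2, Oas1a with Oas1g, and the H2 genes), or by overlapping or antisense genes, could therefore have been split or counted on either gene. The p-value column of the authors' deposited table was read as an unadjusted p of their own comparison of the groups.

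The recovered reads gave the depth. Between 40092665 and 41608435 reads per library were assigned to the genes of the table, and the deepest library had 1.04 times the relative depth of the shallowest. Between 9741 and 9946 genes per library reached 1 FPKM. Libraries of the same group differed by more than sampling noise, with a chi-square per gene of 6.00 to 15.3, so none was treated as a duplicate. Libraries of different groups differed by 160 to 186 on the same measure.

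Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend and without robust weights, over the 9947 genes with at least 1 FPKM in 3 or more libraries. The Benjamini-Hochberg threshold was an adjusted p of 0.05. The fold change from that fit is on the log2(FPKM + 1) scale and understates the change of low genes, so group means in FPKM are given with their SD (n = 3) beside it. A count-based test had been planned in case the table held counts. As it held FPKM, the alternative planned for that unit was used. With 3 libraries against 3, an exact permutation test of a single gene cannot go below a two-sided p of 0.1, which is why no such test is reported.

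Before the data were examined, 32 gene lists were fixed, together with the rule for the genes to be named. The rule took Pten, the 10 genes with the highest and the 10 with the lowest log2 fold change among called genes with at least 5 FPKM in the higher group and no overlap between groups, and from each list the up to 4 members with the smallest p. Predicted genes, ribosomal pseudogenes and immunoglobulin or T-cell receptor segments were passed over in the 10 highest and 10 lowest. Other list members were named to give a level. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry. Lists with fewer than 5 tested members got no set test, which left 26 lists. Mitochondrially encoded genes carry other symbols in the table than in the list and were matched by position. A further 4 lists were written after the first results had been seen and are used only in the closing observations.

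Gene positions are those of GENCODE M21, which annotates the mm10 build. Of the 17004 symbols, 15606 were found there, and 16773 (98.6%) in the RefSeq gene table of the same assembly. The figures were drawn with matplotlib 3.10.9.

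The fit was tested on simulated data before use, with 200 of the 9947 genes changed in each of 20 simulations of the comparison. It recovered 58.8% of genes changed by 0.25, 98.9% of those changed by 0.5 and 99.9% of those changed by 1 on the log2 scale, and 5.82% of its calls were false. The glycolysis list, the only one raised, by 0.3, was called in 100% of simulations, and lists left alone had a camera p under 0.05 in 5% of them. Simulated genes varied independently, whereas the correlation estimated within real lists reached 0.647 (granulocyte markers). The 5% therefore does not cover lists whose members vary together.

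The alternatives were a block for the replicate number, each library left out in turn, upper-quartile scaling, no filter, a stricter filter of 5 FPKM, pseudocounts of 0.1 and 5, an adjusted p of 0.01, a minimum change of 2-fold, an estimated correlation and fry. After the data had been seen, limma's voom on the recovered reads and a scaling that takes Lyz2 out of the totals were added. All 17004 genes were in the table of values, and the 7057 genes under the filter were left out of the tests.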

Results

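Gene expression was compared between mouse bone marrow-derived macrophages labelled WT and those labelled PTEN KO, to describe how their transcripts differ. PTEN is a lipid phosphatase that opposes PI3K signalling. The study as a whole concerns macrophage PTEN in intestinal neurogenesis and inflammation. Marrow cells had been cultured with GM-CSF, a cytokine that drives myeloid precursors towards macrophages and dendritic-like cells, and 3 libraries per genotype were sequenced. Between 40092665 and 41608435 reads per library fell on the 17004 genes of the table.

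Pten transcript was lower in all 3 PTEN KO libraries (5.64, 5.27 and 5.24 FPKM) than in the 3 WT libraries (8.35, 8.97 and 8.67 FPKM), but was not lost. It averaged 8.66 ± 0.312 FPKM (SD, n = 3) in WT and 5.39 ± 0.222 FPKM (SD, n = 3) in PTEN KO, or 62.2% of the WT level, and a library held between 1988 and 3371 reads of the gene. The log2 fold change was -0.60 with a standard error of 0.0540 (limma-trend, Benjamini-Hochberg adjusted p = 2.68e-05). Pten lies on chromosome 19 of mm10 from 32757497 to 32826160, and a value per gene sums the reads of all its exons, so it cannot show whether the remaining transcript lacks a part. A far larger loss was seen in Lyz2, the lysozyme gene of myeloid cells on chromosome 10 (117277331 to 117282321). Lyz2 fell from 19648 ± 316 FPKM (SD, n = 3) in WT to 74.1 ± 3.47 FPKM (SD, n = 3) in PTEN KO, 265-fold, and its share of all reads in the table went from 2.09% to 0.00789%. The neighbouring Lyz1, whose sequence is close to that of Lyz2, fell 15.0-fold from 33.6 to 2.24 FPKM and may share reads with it. Because every PTEN KO library and no WT library lacked most Lyz2 transcript, no comparison here separates the genotype from the near absence of Lyz2.

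**Figure D1:**
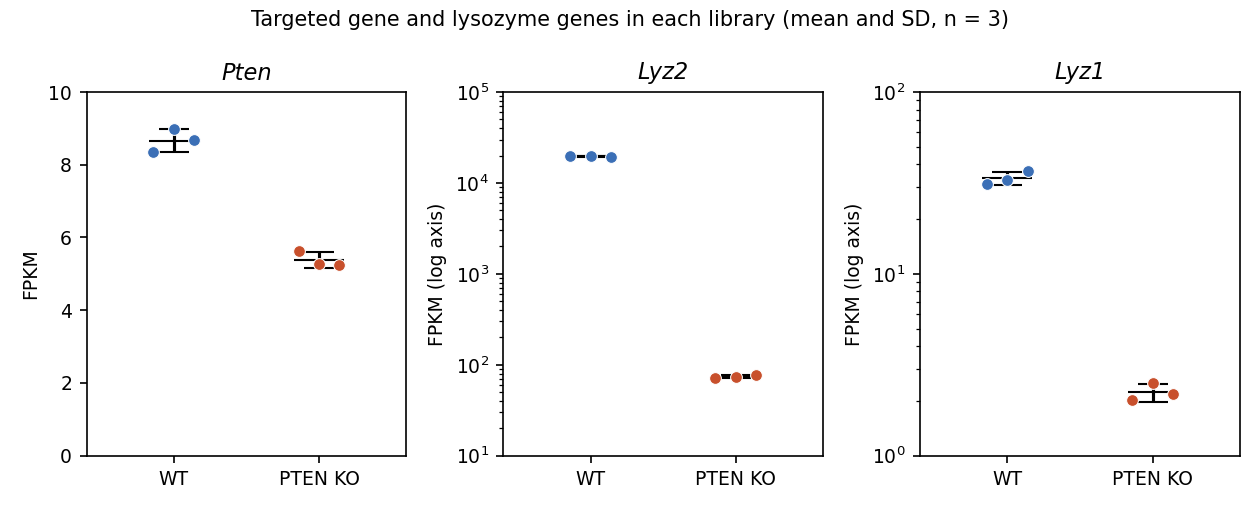
Expression of Pten (linear axis), Lyz2 and Lyz1 (log axes) in FPKM in the 3 WT and 3 PTEN KO libraries, with points for libraries and bars for mean and SD. The 3 PTEN KO libraries lay between 5.24 and 5.64 FPKM for Pten, against 8.35 to 8.97 FPKM in WT, and between 71.5 and 78.0 FPKM for Lyz2, against 19297 to 19911 FPKM.

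The chemokine genes Ccl12, Ccl7, Ccl8 and Pf4 were 4 of the 10 genes with the highest log2 fold change in PTEN KO. Ccl12, a monocyte-attracting chemokine, rose from 2.13 ± 0.581 to 86.3 ± 8.66 FPKM, or 40.5-fold. Ccl7, from the same cluster of chemokine genes, rose 9.38-fold from 51.1 ± 4.28 to 480 ± 44.8 FPKM, and Ccl8 rose 5.64-fold from 4.26 ± 0.952 FPKM. Pf4, the chemokine platelet factor 4, rose 5.73-fold from 78.2 ± 7.26 to 448 ± 30.6 FPKM. Col18a1, which encodes the collagen that gives rise to endostatin, rose 20.8-fold from 0.307 ± 0.0438 to 6.39 ± 0.515 FPKM. The scavenger receptor Stab1, the folate receptor Folr2, the secreted scavenger protein Cd5l and the carbonyl reductase Cbr2 rose between 4.26-fold (Cd5l) and 5.6-fold (Folr2). The last of the 10 was Ltf, the granule protein lactotransferrin, at 13.3 ± 5.84 FPKM in WT and 44.2 ± 10.3 FPKM in PTEN KO. Ltf stands in the list of neutrophil and granulocyte precursor markers. Within each group it was highest in WT replicate 2 (19.9 FPKM) and PTEN KO replicate 1 (56.0 FPKM). In limma-trend these 10 genes had Benjamini-Hochberg adjusted p-values from 6.11e-09 (Cd5l) to 5.13e-04 (Ltf).

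Besides Lyz2 and Lyz1, the lowest log2 fold change on the log2(FPKM + 1) scale was that of Mamdc2 (-2.86), from 34.7 ± 1.27 to 4.0 ± 0.992 FPKM (8.68-fold). Ifngr1, which encodes the ligand-binding chain of the interferon-gamma receptor, fell 5.18-fold from 56.7 ± 3.00 to 10.9 ± 0.959 FPKM. Pdcd1lg2, which encodes the inhibitory ligand PD-L2, fell 4.43-fold from 11 ± 0.746 to 2.49 ± 0.219 FPKM. The vitamin D receptor gene Vdr fell 4.50-fold, Bex1 9.16-fold, Lrrc32 4.46-fold, Pianp 3.76-fold and the adhesion receptor gene Adgre5 3.06-fold. Pdcd1lg2 and Mamdc2 lie on chromosome 19, 3.35 and 9.42 Mb from Pten. Their limma-trend adjusted p-values (Benjamini-Hochberg) were 1.50e-07 and 2.74e-07.

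In all, 3738 of the 9947 genes tested differed between the genotypes (limma-trend, Benjamini-Hochberg), 1790 higher and 1948 lower in PTEN KO. Most of these changes were small: 3222 of them (86.2%) were under 1.5-fold and 138 reached 2-fold on the log2(FPKM + 1) scale, 74 higher and 64 lower. The values of the groups did not overlap for 3675 of the called genes and for 4983 of all tested genes, where chance gives 10%. The first principal component held 78.5% of the variance and parted the genotypes. The second held 9.13% and set PTEN KO replicate 1 (-8.99) and WT replicate 2 (-5.18) apart from the other 4 libraries (2.29 to 5.95). Without PTEN KO replicate 1, 3850 genes were called, and without WT replicate 2, 2824. Per the authors' deposited p-values, 5450 of 17004 genes had an unadjusted p under 0.05, and 3357 (89.8%) of the genes called here passed when those p-values were adjusted by Benjamini-Hochberg.

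**Figure D2:**
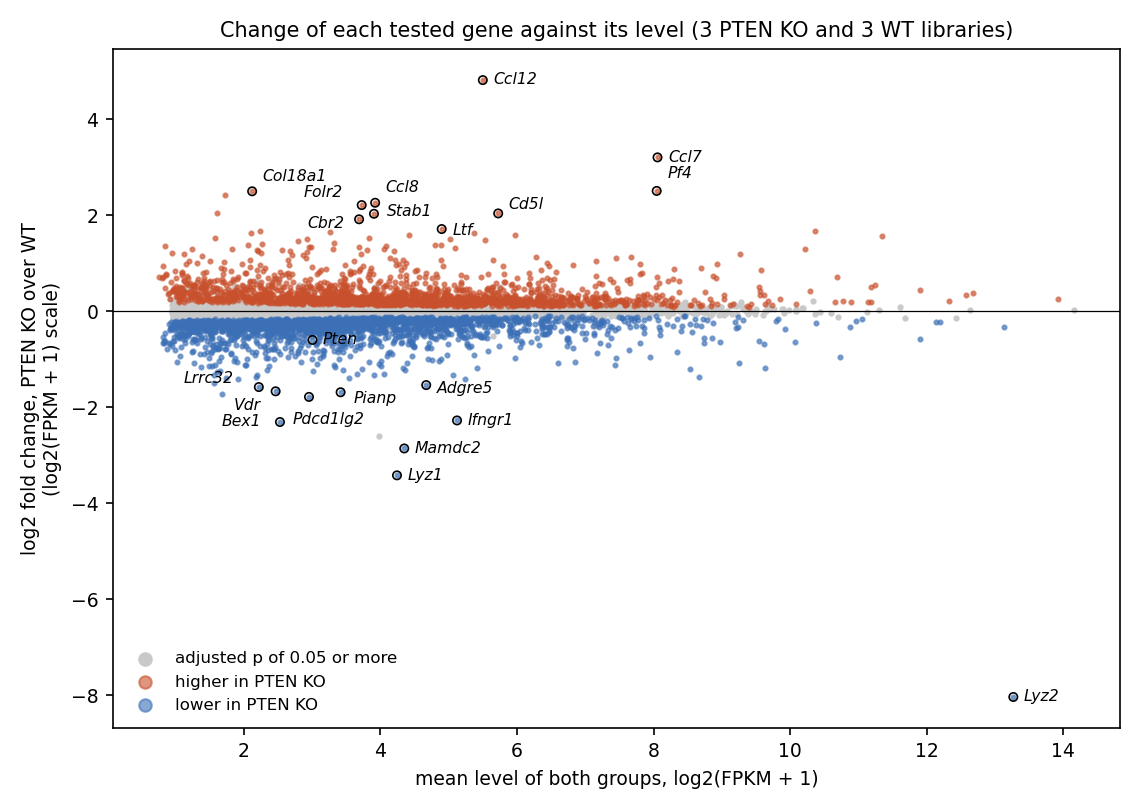
The log2 fold change of each of the 9947 tested genes (PTEN KO over WT, log2(FPKM + 1) scale) against its mean level in log2(FPKM + 1), with genes higher in PTEN KO in orange, lower in blue and all others in grey. Circles mark Pten and the 10 genes with the highest and lowest fold change named by the rule, from Ccl12 at 4.81 to Lyz2 at -8.03.

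Genes of MHC class II antigen presentation fell together. Of 10 tested members 8 were lower and 0 higher in PTEN KO, and 8 lower and 1 higher adjusted over the list alone. H2-Aa fell from 1106 ± 71.7 to 485 ± 8.76 FPKM (2.28-fold), H2-Eb1 from 517 ± 46.1 to 223 ± 2.72 FPKM (2.32-fold) and H2-Ab1 from 825 ± 80.8 to 391 ± 10.0 FPKM (2.11-fold). Ciita, the master activator of these genes, fell from 7.25 to 3.26 FPKM, Cd74, the invariant chain, from 2248 to 1150 FPKM, and H2-DMa from 40 to 20.6 FPKM, while Ifi30 stood at 537 and 581 FPKM and did not pass. The list had the smallest p of the 26 tested (camera, adjusted p = 4.76e-06), but adjusted p = 0.227 with an estimated correlation. Of the 8 dendritic cell markers that reached the filter, 5 were lower and 1 was higher, the same numbers adjusted over the list alone (camera, adjusted p = 0.0116; adjusted p = 0.227 with an estimated correlation). Among them Clec9a, a receptor of cross-presenting dendritic cells, fell from 5.51 ± 0.492 to 1.51 ± 0.207 FPKM, Cd209a from 3.93 to 0.492 FPKM, the transcription factor Batf3 from 15.4 to 8.56 FPKM and the chemokine Ccl17 from 58.1 to 25.2 FPKM, while Cd24a rose from 13.8 to 23.3 FPKM. Without WT replicate 1, 4 of 7 dendritic cell markers were lower and 0 higher. Without WT replicate 2, or without WT replicate 3, 3 of 7 were lower and 1 was higher. In each of these settings Cd209a, under 1 FPKM in PTEN KO, no longer reached the filter and was not tested. The camera call was lost with no filter (4 of 15 lower, 0 higher, median slightly above 0, adjusted p = 0.128) and with the filter of 5 FPKM (adjusted p = 0.164).

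Genes tied to GM-CSF signalling and alveolar macrophages were mostly lower, with 12 of 21 lower and 5 higher, also when adjusted over the list alone (camera, adjusted p = 0.0141; adjusted p = 0.227 with an estimated correlation). Csf2rb and Csf2rb2, which encode beta chains of the GM-CSF receptor family, fell from 551 to 374 FPKM and from 198 to 122 FPKM. Cish, a feedback inhibitor induced by cytokine receptors, fell from 27.4 to 12.4 FPKM and the lectin gene Siglecf fell 3.44-fold from 5.51 FPKM. The scavenger receptor Marco rose 3.73-fold, and the fatty acid-binding protein Fabp4 rose from 149 to 294 FPKM. Pparg, a regulator of alveolar macrophage identity, stood at 13.1 and 12.5 FPKM and did not pass.

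General macrophage markers were mostly higher apart from Lyz2. Of 16 markers 9 were higher and 3 lower, also when adjusted over the list alone, and the median log2 fold change was 0.28. The mean was -0.22 because of Lyz2, camera gave the direction up (adjusted p = 0.0268; adjusted p = 0.424 with an estimated correlation) and fry the direction down. The Fc receptor gene Fcgr1 rose 2.93-fold from 15.9 to 46.7 FPKM, the transcription factor gene Mafb 2.14-fold, and Adgre1, which encodes F4/80, from 208 to 266 FPKM. Cd14 fell 1.90-fold and Csf1r, the M-CSF receptor gene, fell from 261 to 204 FPKM. In the complement list 6 of 11 members were higher and 1 lower, also when adjusted over the list alone (camera, adjusted p = 0.0156; adjusted p = 0.227 with an estimated correlation). C1qa, C1qb and C1qc, the subunits of C1q, rose 1.58-fold, 1.43-fold and 1.6-fold, and C5ar1, a receptor of the fragment C5a, rose from 27.7 to 46.3 FPKM. The list shares C1qa, C1qb, C1qc and Itgam with the macrophage markers, whose call was lost with the filter of 5 FPKM (camera, adjusted p = 0.0895). Without PTEN KO replicate 1, 2 complement genes were lower.

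The neurotrophic and growth factors, the group nearest to the study's interest in neurogenesis, were higher for 10 and lower for 4 of 18 tested members, also when adjusted over the list alone (camera, adjusted p = 0.0154; adjusted p = 0.227 with an estimated correlation). Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 1313 ± 65.1 to 3912 ± 244 FPKM (2.98-fold). Gas6, a ligand of the receptors Axl and Mertk, rose 2.74-fold from 8.56 ± 0.141 to 23.4 ± 1.25 FPKM, Pdgfc 3.21-fold from 6.30 ± 0.356 to 20.2 ± 2.18 FPKM and Igf1 1.74-fold from 52.2 ± 1.11 to 90.9 ± 2.64 FPKM. Csf1, Pros1 and the semaphorins Sema4a and Sema4d were lower, with Csf1 falling from 38.1 to 23.6 FPKM. Of the 44 factors listed, 34 were in the table, and those under the filter were not tested. Among the untested, Bdnf and Bmp2 lay below 0.03 FPKM in every library, and Nrtn, Cntf and Lif reached at most 0.0663, 0.123 and 0.0316 FPKM. With no filter on level the list no longer passed camera (adjusted p = 0.0848).

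Chemokine receptors and ligands other than those of the inflammatory list were higher for 7 and lower for 4 of 15, also when adjusted over the list alone, and the list narrowly missed the camera threshold (adjusted p = 0.0598; adjusted p = 0.587 with an estimated correlation), which it passed without WT replicate 1, WT replicate 2 or PTEN KO replicate 2 and in 2 other settings (0.0324 to 0.0485, out of 0.0324 to 0.103 over all settings). Cxcl16 fell from 22.5 to 8.53 FPKM, and Ccr2 stood at 4.73 and 5.51 FPKM and did not pass. The inflammatory list split evenly, with 7 of 22 higher and 7 lower (7 and 8 adjusted over the list alone; camera, adjusted p = 0.538). Ccl2 rose from 692 ± 3.67 to 1694 ± 119 FPKM (2.45-fold), Ccl3 and Ccl4 rose 1.6-fold and 1.57-fold, and the interleukin-1 receptor antagonist gene Il1rn rose 1.65-fold. Il1b fell from 4.49 to 1.77 FPKM and Tnf from 25.9 to 17.8 FPKM. Alternative activation genes were also divided, with 6 of 19 higher and 8 lower (6 and 9 adjusted over the list alone; camera, adjusted p = 0.396). The transferrin receptor gene Tfrc rose 3.22-fold and the mannose receptor gene Mrc1 rose from 232 to 361 FPKM, while Irf4 fell 2.15-fold and Ccl17 2.30-fold. The number of higher genes in this list was 3 without WT replicate 1 and 3 without PTEN KO replicate 2.

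Toll-like receptor and NF-kB genes were lower for 15 and higher for 2 of 28 (16 and 2 adjusted over the list alone; camera, adjusted p = 0.0116; adjusted p = 0.625 with an estimated correlation). The adaptor gene Ticam2 fell from 10.1 to 6.35 FPKM and Nfkb1 from 23.6 to 18.1 FPKM, while Tlr1 rose from 9.58 to 17 FPKM, Tlr13 rose 1.22-fold and Tlr4 stood at 13.6 and 12.0 FPKM without passing. Interferon-stimulated genes were higher for 15 and lower for 4 of 28, also when adjusted over the list alone (camera, adjusted p = 0.0282; adjusted p = 0.625 with an estimated correlation). Rtp4 rose 3.81-fold, Oas1a from 15.6 to 23.8 FPKM and Bst2 from 70.9 to 92.6 FPKM. The 4 lower members were the guanylate-binding protein genes Gbp2 (2.75-fold), Gbp3 (1.87-fold) and Gbp5 (2.22-fold) and the GTPase gene Ifi47, all of which are known to be induced by interferon-gamma. Under the filter of 5 FPKM 6 of 14 interferon-stimulated genes were higher and 2 lower, and the camera call was lost (adjusted p = 0.397).

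Within the PI3K, AKT and mTOR pathway, which PTEN opposes, 11 of 29 genes were lower and 5 higher (12 and 5 adjusted over the list alone; camera, adjusted p = 0.0517; adjusted p = 0.625 with an estimated correlation). Akt3 fell from 4.84 ± 0.120 to 2.08 ± 0.0305 FPKM (2.32-fold), the phosphatase gene Phlpp1 fell 1.98-fold, and the PI3K subunit genes Pik3cd and Pik3r5 fell 1.52-fold and 1.44-fold. Akt1 stood at 101 and 95.3 FPKM and did not pass. The higher genes numbered 2 without WT replicate 1, without WT replicate 3 or without PTEN KO replicate 2, 3 without WT replicate 2, without PTEN KO replicate 1 or with no filter, and 2 with Lyz2 taken out of the totals. The list passed camera without WT replicate 1, WT replicate 2 or PTEN KO replicate 1 and in 2 other settings (adjusted p from 0.0370 to 0.0498). FoxO target genes were lower for 12 and higher for 4 of 22, also when adjusted over the list alone (camera, adjusted p = 0.0443; adjusted p = 0.625 with an estimated correlation). Pink1 fell from 14.8 to 8.52 FPKM and Irs2 from 4.61 to 2.57 FPKM, while Sesn1, Gadd45a and S1pr1 rose 1.83-fold, 2.11-fold and 4.96-fold. The FoxO call was lost in 7 other settings, among them without each library except PTEN KO replicate 1, where its adjusted p in camera ran from 0.0570 to 0.108, and with the filter of 5 FPKM, where 6 of 13 genes were lower.

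**Figure D3:**
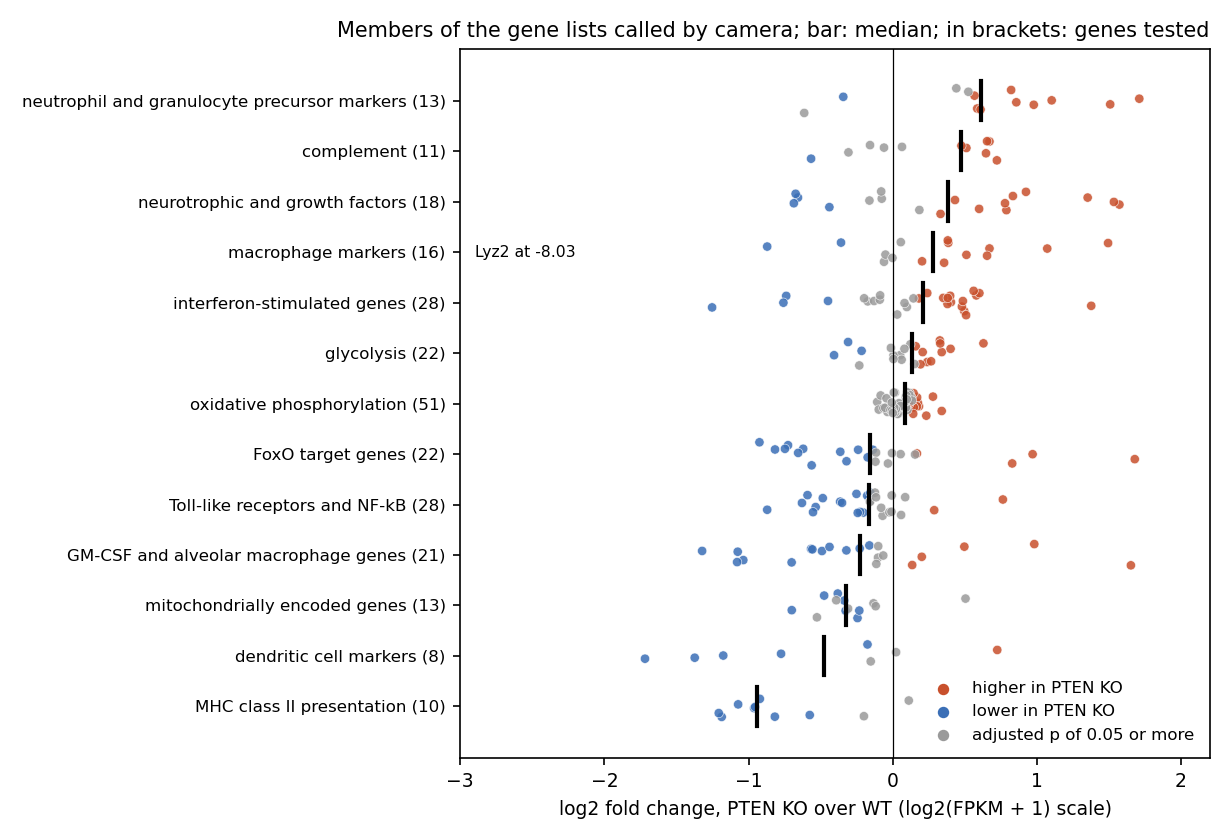
The log2 fold change (PTEN KO over WT, log2(FPKM + 1) scale) of each tested member of the 13 gene lists called by camera at the preset correlation, with genes higher in PTEN KO in orange, lower in blue, others in grey and the median as a bar. Medians ran from -0.94 for MHC class II presentation to 0.61 for the granulocyte markers, and Lyz2 at -8.03 lies outside the axis.

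Glycolysis genes were higher for 10 and lower for 3 of 22 (10 and 4 adjusted over the list alone; camera, adjusted p = 0.0156; adjusted p = 0.625 with an estimated correlation). Pkm rose from 284 ± 2.89 to 375 ± 8.81 FPKM, Tpi1 from 205 to 257 FPKM and the regulator Pfkfb3 1.62-fold, while Pfkp fell from 45.5 to 34.1 FPKM. With the filter of 5 FPKM the call was lost (camera, adjusted p = 0.0554). Oxidative phosphorylation genes encoded in the nucleus were higher for 15 and lower for 0 of 51, also when adjusted over the list alone (camera, adjusted p = 0.0116; adjusted p = 0.625 with an estimated correlation). These changes were small, such as Ndufa2 from 70.0 to 85.1 FPKM and Ndufb8 from 51.5 to 58.6 FPKM, with log2 fold changes of 0.23 for Ndufa8 and 0.17 for Ndufa10. Leaving out PTEN KO replicate 1 gave 18 higher genes, leaving out any other library gave 6 to 9 (and 2 lower without PTEN KO replicate 3), upper-quartile scaling gave 9 higher and 1 lower, and taking Lyz2 out of the totals gave 7 higher and 1 lower. Without WT replicate 2 or without PTEN KO replicate 3 the list lost its call (camera, adjusted p = 0.0562 and 0.0549). The 13 mitochondrially encoded genes went the other way, with 7 lower and 0 higher, also when adjusted over the list alone (camera, adjusted p = 0.0156; adjusted p = 0.625 with an estimated correlation). COX1 fell from 10040 ± 378 to 7952 ± 255 FPKM and ND5 from 2097 to 1670 FPKM, and ND4 and ND4L were also lower (log2 fold changes of -0.24 and -0.38). With no filter on level 3 of these genes were lower. The mitochondrially encoded genes took 3.26 ± 0.180% of reads in WT and 2.69 ± 0.104% in PTEN KO (SD, n = 3).

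Lipid and amino acid synthesis showed no common direction by camera. In fatty acid synthesis 5 of 14 genes were higher and 1 lower (5 and 2 adjusted over the list alone; adjusted p = 0.131), with the desaturase genes Scd2, Scd1 and Fads2 rising 1.67-fold, 2.73-fold and 2.28-fold and Acss2 falling 1.95-fold. The list had 2 lower genes under upper-quartile scaling or with Lyz2 taken out of the totals, and 3 higher with the filter of 5 FPKM. In cholesterol synthesis 5 of 22 were higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.141), Sqle rose from 40.8 to 50.7 FPKM and Dhcr7 fell 1.32-fold to 15.1 FPKM, with Insig1 and Hsd17b7 also higher (log2 fold changes of 0.35 and 0.36). Without PTEN KO replicate 1 the cholesterol list had 10 higher and 2 lower genes and passed camera (adjusted p = 0.0125), and without PTEN KO replicate 2 it had 3 higher and 2 lower. Of 25 ATF4 and amino acid genes 6 were higher and 2 lower, also when adjusted over the list alone (camera, adjusted p = 0.399), where Slc7a11, the cystine transporter gene, fell 1.99-fold, Nupr1 was lower (log2 fold change -0.82), Gpt2 rose from 2.49 to 3.72 FPKM and Sars was higher (log2 fold change 0.30). The median of this list was 0.08 and its mean -0.01, with camera giving the direction up.

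Genes of uptake, degradation and matrix turnover changed in both directions. Of 29 phagocytosis and scavenger receptor genes 10 were higher and 10 lower, also when adjusted over the list alone (camera, adjusted p = 0.538), with Cd36 rising from 350 to 584 FPKM and the inhibitory Fc receptor gene Fcgr2b falling 2.19-fold from 237 to 108 FPKM. Of 34 lysosome and autophagy genes 11 were higher and 10 lower, also when adjusted over the list alone (camera, adjusted p = 0.622). The protease gene Ctsl rose 3.19-fold from 625 ± 22.5 to 1996 ± 72.2 FPKM, Ctsb rose 1.45-fold and Plin2 1.32-fold, and Gabarapl1 fell 1.64-fold. The median of this list was slightly below 0 and its mean was 0.05. The higher lysosome genes numbered 7 without WT replicate 2 and 7 without PTEN KO replicate 2. Of 18 matrix and protease genes 8 were higher and 7 lower, also when adjusted over the list alone (camera, adjusted p = 0.538), with Adam8, Mmp13 and Plau rising 1.86-fold, 1.73-fold and 1.62-fold and Mmp19 falling 1.79-fold. Of 9 osteoclast markers 2 were higher and 4 lower, also when adjusted over the list alone (camera, adjusted p = 0.534). Dcstamp, required for cell fusion, fell 2.73-fold from 54.0 to 19.8 FPKM, Acp5 fell 1.79-fold, and Ctsk and Tnfrsf11a, which encodes the receptor RANK, were higher (log2 fold changes of 0.60 and 0.61).

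Cell cycle genes differed little, with 3 of 33 higher and 2 lower (1 and 1 adjusted over the list alone; camera, adjusted p = 0.396). The mitotic checkpoint gene Bub1b fell from 6.59 to 3.91 FPKM, Pcna rose from 176 to 202 FPKM, and Ccne1 and Ccnb1 were higher (log2 fold changes of 0.27 and 0.25). Without PTEN KO replicate 1 there were 7 higher genes and 1 lower, without WT replicate 3 or PTEN KO replicate 2 there were 1 higher and 2 lower, and without any 1 of the other 3 libraries 2 higher and 1 lower. Pcna no longer passed without WT replicate 2, WT replicate 3, PTEN KO replicate 2 or PTEN KO replicate 3, and Ccnb1 without WT replicate 1, WT replicate 3 or PTEN KO replicate 2. Immediate-early and heat shock genes, which respond to handling, were higher for 4 and lower for 2 of 14 (5 and 2 adjusted over the list alone; camera, adjusted p = 0.538), with Jund falling from 38.6 to 32.1 FPKM, Zfp36 rising from 71.9 to 97 FPKM, and Jun and Hsp90aa1 higher by log2 fold changes of 0.16 and 0.17. The list had 2 higher genes without WT replicate 1, WT replicate 3, PTEN KO replicate 2 or PTEN KO replicate 3, and without any of these 4 Zfp36 no longer passed. The median of this list was slightly below 0 and its mean was 0.11.

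Markers of other cells were measured beside these groups. Neutrophil and granulocyte precursor markers were higher for 9 and lower for 1 of 13 (9 and 2 adjusted over the list alone; camera, adjusted p = 0.0119; adjusted p = 0.625 with an estimated correlation). Camp rose from 3.00 ± 1.27 to 10.2 ± 2.14 FPKM, with the highest value of each group in WT replicate 2 (4.45 FPKM) and PTEN KO replicate 1 (12.6 FPKM), the libraries apart on the second component. Ngp rose from 112 to 234 FPKM, S100a8 from 327 to 641 FPKM and the transcription factor gene Cebpe by a log2 fold change of 0.57, while Mmp8 fell from 663 to 523 FPKM. Without PTEN KO replicate 1, 7 of these markers were higher and 2 lower, and with the filter of 5 FPKM the call was lost (camera, adjusted p = 0.114). No B cell and no T or NK cell marker reached the filter. Of 3 tested mast cell, basophil and eosinophil markers Gata2 and Hdc were lower and Prg2 higher, of 2 erythroid and megakaryocyte markers Pf4 was higher and Itga2b lower, and the only tested stromal marker, Acta2, did not pass. These counts were also those adjusted over the list alone. Without any 1 of the WT libraries, 1 of 2 mast cell, basophil and eosinophil markers was lower. Gata2, under 1 FPKM in PTEN KO, then no longer reached the filter and was not tested. The Y-linked genes Ddx3y (14.6 and 16.3 FPKM), Kdm5d (4.16 and 3.70 FPKM), Eif2s3y (5.48 and 6.14 FPKM) and Uty (2.25 and 2.32 FPKM) were transcribed in all 6 libraries, while Xist and Tsix were not in the table. In limma-trend 0 of these 4 passed, also when adjusted over the list alone, with Benjamini-Hochberg adjusted p-values from 0.0528 (Ddx3y) to 0.802 (Uty). Ddx3y passed without WT replicate 3 or PTEN KO replicate 2, and Eif2s3y without PTEN KO replicate 1.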

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

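The fits with voom on recovered reads and with Lyz2 taken out of the totals were chosen only after the results were seen. Of the 3738 genes called by limma-trend, 2295 had an adjusted p below 0.01 and 138 changed at least 2-fold, limits stricter by construction. Leaving out 1 library gave 2759 (without PTEN KO replicate 2) to 3850 genes (without PTEN KO replicate 1), a replicate block gave 3310 (with 9 instead of 15 oxidative phosphorylation genes and 3 instead of 5 PI3K-AKT-mTOR genes higher), upper-quartile scaling 3740, no filter 3522 and the filter of 5 FPKM 2889. Pseudocounts of 0.1 and 5 gave 3722 and 3733, voom 3862 and the removal of Lyz2 from the totals 3741, with 39.1% of them higher instead of 47.9%. Each called gene that was tested kept its sign in these settings, and the scalings moved the median of all genes by at most 0.0262. Pten had an adjusted p below 0.05 (limma) in each of these fits, with log2 fold changes from -0.69 (voom) to -0.40 (pseudocount 5), but did not reach the 2-fold limit. Camera called 13 of 26 lists, 7 with the filter of 5 FPKM, which tests fewer genes, 11 to 15 without 1 library and 0 with an estimated correlation, and fry called 15. Fry did not call 4 of the 13 lists (adjusted p = 0.050013 for FoxO targets, 0.0659 for interferon-stimulated genes, 0.0991 for granulocyte markers and 0.113 for oxidative phosphorylation). It called 6 others, namely PI3K-AKT-mTOR, alternative activation, chemokines, phagocytosis, lysosome and osteoclast markers, and gave the macrophage markers the opposite direction, down. With an estimated correlation the smallest adjusted p of a list was 0.227. At the preset correlation, over the filters, scalings, voom, the block and the libraries left out, 15 lists stayed on the same side of the camera threshold and 11 changed side in at least 1 setting. Over the same settings and the pseudocounts, 115 of 121 named genes other than Pten stayed on the same side wherever they were tested. The others were Ccnb1, Pcna, Zfp36 and ND4L, which lost their call, and Ddx3y and Eif2s3y, which gained one. For these lists and genes the cause was not tested. Called and named genes were picked from the main fit of the same libraries, so their stability is not independent support. The replicate numbers were not used to pair samples, as no label says that equal numbers belong together. After the group means were removed, the residuals of equally numbered libraries correlated at -0.25, -0.16 and 0.16. With 3 libraries per group these values can neither show nor exclude a pairing. The alternatives planned for counts (a DESeq2 Wald test, median-of-ratios size factors and a count filter) were planned only for deposited counts, which the table does not hold, and were not run on the recovered reads. The self-test recovered 58.8% of changes of 0.25 on the log2 scale with 200 of 9947 genes changed. As 3738 genes were called in the data, that share does not carry over to them. Small changes may have been missed, but how many is unknown.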

Other observations

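The tests of Lyz2 and of dendritic-like cells, and the 4 gene lists of this part, were chosen only after the results were seen. Genes typical of resident tissue macrophages were higher in PTEN KO for 22 and lower for 1 of 26 tested, also when adjusted over the list alone, with a median log2 fold change of 1.02 (camera, adjusted p = 2.71e-17; adjusted p = 0.00311 with an estimated correlation). The list was written partly from the most changed genes, and 16 of its members stand in other lists, so it is not independent evidence of a direction. Among members not described above, Maf, a transcription factor gene of mature macrophages, rose from 8.58 ± 0.318 to 22.5 ± 0.562 FPKM (SD, n = 3). Vcam1 rose 2.50-fold, F13a1 2.76-fold, Hpgds 2.29-fold and the complement receptor gene Vsig4 3.22-fold. The transferrin gene Trf was the member that fell, from 141 to 82.8 FPKM.

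Cholesterol efflux and iron genes moved in both directions. Of 19 LXR and lipid efflux genes 9 were higher and 4 lower (10 and 4 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.0515; adjusted p = 0.176 with an estimated correlation). The cholesterol exporter gene Abca1 rose 2.56-fold to 47.5 ± 0.910 FPKM (SD, n = 3) and the LXR alpha gene Nr1h3 1.63-fold, while Apoe, which encodes a lipid-carrying apolipoprotein, fell 2.58-fold from 584 ± 57.1 to 226 ± 9.86 FPKM and Cyp27a1 fell 1.96-fold. The lower genes numbered 2 without WT replicate 1, 2 without WT replicate 2 and 2 with no filter. Of 18 iron handling genes 6 were higher and 5 lower (6 and 6 adjusted over the list alone; camera, adjusted p = 0.324). Hmox1, the haem-degrading enzyme gene, rose 2.28-fold from 375 ± 11.9 to 855 ± 13.7 FPKM, and the iron exporter gene Slc40a1 rose 1.68-fold.

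Lyz2 stood at 0.377% of the WT mean in PTEN KO, with 0.364 to 0.397% in single libraries. Loss of macrophages from the cultures is argued against, as the 15 other macrophage markers had a median log2 fold change of 0.36 (range -0.87 to 1.5). Disruption of 1 of the 2 Lyz2 copies in each cell would leave far more than the 0.377% seen, if the other copy were transcribed as in WT. Whether it was is not known, and the limits of this comparison were set after the value was seen. Disruption of both copies in nearly all cells remains open, since it was proposed from the same 0.377% and no other value here tests it. It could come from a recombinase gene inserted at Lyz2, a hypothesis only, since no label names one, and a biological effect of the PTEN genotype on Lyz2 is confounded with it and was not tested.

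Large changes also lay near Pten and Lyz2. Leaving aside Pten, Lyz2 and Lyz1 themselves, of 136 tested genes within 10 Mb of either, 3 (2.21%) were called with at least 2-fold change, Mamdc2 (-2.86) and Pdcd1lg2 (-1.78) near Pten and Ctdsp2 (-1.03) near Lyz2, against 121 of 9572 others (1.26%). DNA of another strain around the altered genes may explain them, but the odds ratio was 1.76 (95% interval 0.354 to 5.39, exact Fisher p = 0.252), which is too wide to tell. Ifngr1, on the same chromosome as Lyz2, lay outside that window. An effect of PTEN itself on these genes remains open and was not tested.

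The lower MHC class II genes (median log2 ratio -0.96) were set against 2 explanations. Fewer dendritic-like cells could lower them, but 13 dendritic cell markers had a median log2 ratio of -0.18 (-0.84 to 0.76), with 7 lower and 6 higher. Among the higher, Zbtb46, Ccr7, Dpp4 and Fscn1 lay under the filter (at most 0.346 FPKM on average in WT), as did Itgae among the lower. PTEN KO replicate 1 held the highest Ccr7 and Fscn1 of all libraries (1.15 and 1.05 FPKM). Of the 8 markers that reached the filter, 5 were lower and 1 was higher. The most abundant in WT were Ccl17 (58.1 FPKM, and 25.2 FPKM in PTEN KO), Irf8 (18.4 and 16.2 FPKM), Batf3 (15.4 and 8.56 FPKM) and Cd24a (13.8 and 23.3 FPKM). The medians of the markers and the MHC class II genes differed by 0.78 (95% interval -0.05 to 1.78), which does not decide it. These intervals resample genes, not libraries. Without PTEN KO replicate 1 the markers' median was -0.21 (-0.85 to -0.07). Its difference from the MHC class II median, which still used all 6 libraries, had an interval of -0.07 to 1.03. Those intervals met the prediction for fewer dendritic-like cells, written after the results were seen, whereas the intervals over all 6 libraries did not. No other library was left out of this test. The one left out held the highest Ccr7 and Fscn1, both among the higher markers, so the change does not decide the question. Less interferon-gamma signalling, with Ifngr1 lower, predicted lower interferon-gamma-induced genes, whose median log2 fold change was -0.13 with 7 of 20 lower and 1 higher, also when adjusted over the list alone (camera, p = 0.0274, adjusted p = 0.0515; p = 0.286 and adjusted p = 0.346 with an estimated correlation). In camera the list was under 0.05 only unadjusted and at the preset correlation, so that explanation remains a hypothesis. Among the members of the list, Irf1 fell 2.08-fold, Tapbp 1.31-fold and Psmb10 1.30-fold, and Gbp9 rose 1.69-fold. Of the 27 members in the table, 20 reached the filter. In WT the untested Cxcl9, Iigp1 and Tgtp2 reached at most 0.0425, 0.0701 and 0.141 FPKM, so they could hardly fall. Serpina3g, also untested, stood at 0.896 to 1.18 FPKM in WT and 0.297 to 0.398 FPKM in PTEN KO.

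Of the 10 splits of the 6 samples into 3 and 3, 1 called as many genes as the real one, which is the real split itself (3738 genes by limma-trend, with 0 in the highest of the others). These splits are too few for a share under 0.05. Each of the others also put libraries of both genotypes in each group, so the genotype difference widened the spread within groups. Their 0 calls therefore say little.

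Ttr, chosen after its values were seen, varied between libraries of both groups, at 38.1, 9.39 and 15.0 FPKM in WT and 0.0558, 26.1 and 0.0362 FPKM in PTEN KO (limma-trend, Benjamini-Hochberg adjusted p = 0.0875).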
